A study of Rattus norvegicus with 9 samples.

How the data were processed

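RNA sequencing measured gene expression in the medial prefrontal cortex of Wistar Kyoto rats, a strain often used as a model of depression-like behaviour. The 9 libraries fall into 3 groups of 3, named Control, K4 and Ketamine in the titles, all collected on day 15. Per the labels, Control rats were left untreated, K4 was given through an intravenous cannula and ketamine under the skin, each for 7 days, and both were then withdrawn for 7 days. The labels give no dose, no vehicle, no time of dissection and no statement that each library came from a separate animal, so every p-value measures only the spread between these libraries. Per the labels, the libraries were made from total RNA with a poly(A)-selecting kit that keeps strand.

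Per the submitters' processing notes, bcl2fastq 2.20.0, Trimmomatic (version not given), HISAT2 2.1.0 and StringTie 2.1.3b were used with genome build rn6; the notes give neither the order nor the role of each tool. The authors deposited raw read counts per gene for all 9 libraries, and the tool and strand setting that made them are not given in the sources used here. Per the file headers, the authors also deposited FPKM and TPM per gene for each library. In each library the deposited TPM summed to the same total and stood in a fixed ratio to the deposited FPKM. The count table held 37991 genes with NCBI gene IDs and no coordinates, and 12287 of them had no count in any library. Spreadsheet dates stood in place of 27 gene symbols, which were restored through their gene IDs. Gene names came from the deposited table and from a RefSeq table of a later assembly (GRCr8), used for names only, in which 29216 of the gene IDs were found. Because the strand setting is unknown, counts of genes with an antisense or overlapping partner are uncertain, as are those of ribosomal protein, haemoglobin and other genes with near-identical copies or pseudogenes.

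Library totals ranged from 27122207 to 42731004 counts. Counts were analysed in R 4.3.3 with edgeR 4.0.16, after TMM normalisation and filterByExpr by group (minimum count 10, minimum total 15), which left 18047 genes. All 9 libraries were fitted together with 3 groups by a robust quasi-likelihood model. Each pair of groups, and all 3 groups together, were compared with the quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The common biological coefficient of variation was 10.2%. Normalised read counts are given as CPM (counts scaled to library size, mean ± SD, n = 3 libraries per group), and intervals of log2 fold changes cover 95%.

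Before the data were examined, the comparisons, the test, the settings to vary, 29 gene lists and the rule for named genes were fixed. The rule takes, for each pair of groups and each direction, the 8 called genes with the largest log2 fold change and the 4 with the smallest p, among genes with a mean log2 CPM of at least 0, a gene symbol and no overlap between the groups. Where a direction had fewer than 5 such genes, those with the smallest p were added up to 5 and are given as values. For each list it takes up to 4 called members by smallest p, or the member with the smallest p where none was called. It also takes a fixed set that includes Bdnf, Ntrk2, Grin1, Grin2a, Grin2b, Gria1, Gria2, Fos, Arc, Npas4 and Egr1. Genes outside the rule are marked as chosen after their values were seen, and some genes that the rule takes are not reported here. The lists cover immediate early genes, ionotropic and metabotropic glutamate receptors, the postsynaptic density, synaptic vesicles, GABA signalling, monoamine receptors, opioid genes, neurotrophin and mTOR signalling, glucocorticoid-responsive and stress-axis genes, ion channels, the circadian clock, heat shock, interferon and inflammation, perineuronal nets, oxidative phosphorylation and ribosomal proteins. They also cover markers of interneurons, excitatory layers, astrocytes, microglia, oligodendrocytes, oligodendrocyte precursors, endothelial and mural cells, meninges, choroid plexus, ependyma, striatal neurons and blood cells. Of 582 list entries, 581 matched a gene in the table. Lists were tested against all other genes with camera (limma 3.58.1, preset correlation 0.01) and Benjamini-Hochberg adjustment over the 29 lists, again with a correlation estimated from the data, and with fry.

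The test was tried first on simulated counts for all 9 libraries, with the real library sizes and dispersions. Each gene was drawn from its mean over all 9 libraries, and changes were added to the first group of each pair. For K4 against Control, edgeR recovered 20% of 50 genes changed 1.25-fold, 59.2% of 49 changed 1.5-fold, 84% of 50 changed 2-fold and 85.7% of 49 changed 3-fold, with 6 false calls among 17656 unchanged genes. For Ketamine against Control it recovered 14%, 67.3%, 74% and 88% at the same sizes, with 9 false calls among 17639. For K4 against Ketamine it recovered 12.2%, 60%, 78% and 94%, with 15 false calls among 17622. Most changes of 1.25-fold were thus missed in these simulations. Far fewer genes were changed there than were called in the data, which makes the adjusted threshold stricter. The shares recovered therefore need not hold for the data. Calls against Control there had median absolute log2 fold changes of 0.36 (K4) and 0.37 (Ketamine).

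The settings varied were DESeq2 size factors and upper quartile scaling, no filter, a stricter filter, a fit without the robust setting, the replicate number as a block, the DESeq2 1.42.0 test, limma-voom with quality weights, only the 6 libraries compared, an adjusted p below 0.1, a fold minimum of 1.5, the deposited FPKM plus 1 or 0.1 and the deposited TPM plus 1, and leaving out each library in turn. The following alternatives were chosen after seeing the data. A length offset removed each library's trend over transcript length, by loess with span 0.5. The trend was taken on log2 CPM minus each gene's mean over the libraries, and the length was the one implied by the deposited counts and FPKM. Counts were also thinned at random to the smallest library total, and the fits were repeated without Control replicate 2 and K4 replicate 2. On simulated counts with a linear length trend added to the Control libraries only, K4 against Control was tested. The offset recovered 149 of 197 changed genes with 9 false calls, against 154 with 24 false calls without it. Ketamine against Control, where the slopes over length differed more, was not simulated with a trend. Comparisons that share the Control libraries were set beside 20 simulations with no treatment effect. GC content was not checked because no sequence of the build was among the sources used here, and reads were not analysed here. Other software was Python 3.11.15 with pandas 2.3.3.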

Results

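Gene expression was measured by RNA sequencing in the medial prefrontal cortex of rats given K4, a compound named here only by its code, or ketamine, an NMDA receptor antagonist with antidepressant use, for 7 days and then kept without it for 7 days. Untreated rats served as Control, and each group held 3 libraries. Library totals were 42729200, 42731004 and 40863756 counts in Control replicates 1 to 3, 32585900, 32735785 and 28495399 in K4, and 32158089, 27122207 and 33837450 in Ketamine. The 13 mitochondrially encoded protein genes took 15.1% ± 3.68 of the counts in Control (SD, n = 3), 10.8% ± 0.518 in K4 and 11.4% ± 0.652 in Ketamine. The libraries also differed in how counts depended on transcript length. Slopes over length were taken on log2 CPM minus each gene's mean over all 9 libraries, so only differences between libraries have meaning. Per doubling of length they were 0.060, 0.043 and 0.070 in Control, 0.002, −0.020 and −0.010 in K4, and −0.018, −0.066 and −0.061 in Ketamine. Against Control, short transcripts therefore had higher and long transcripts lower log2 fold changes, with medians of 0.13 (K4) and 0.21 (Ketamine) in the 1805 genes with the shortest transcripts and −0.15 and −0.23 in the 1805 with the longest. A length offset for this trend was applied as a further fit.

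**Figure D1:**
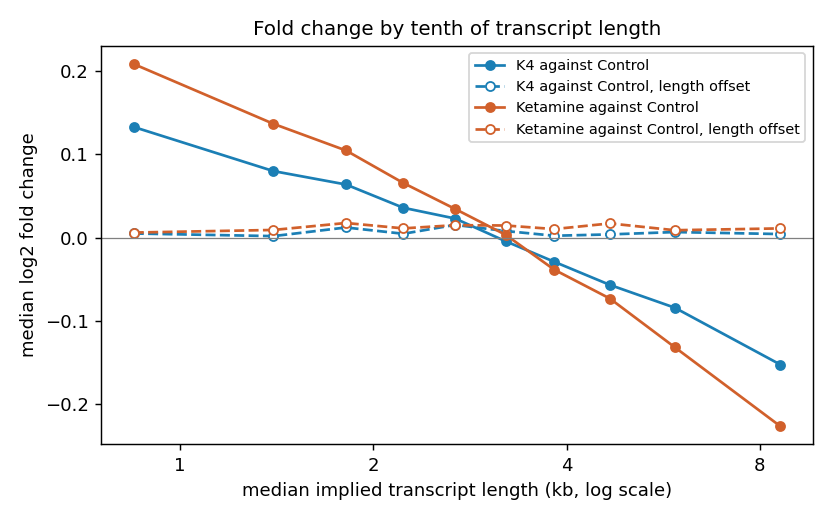
Median log2 fold change against Control (vertical axis) in 10 groups of equal size of the tested genes ordered by implied transcript length (horizontal axis, kb, log scale), for K4 and Ketamine, without (filled) and with (open) the length offset. Medians run from 0.13 and 0.21 in the shortest group to −0.15 and −0.23 in the longest, and lie near 0 with the offset.

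K4 against Control asks which expression differences were present after a week of K4 and a week without it. No library was taken at the end of treatment, so changes that lasted cannot be told from changes that arose after withdrawal. Sorcs3, a postsynaptic sorting receptor, Cyp26b1, which breaks down retinoic acid, and Dohh, an enzyme of hypusine synthesis, were higher after K4. Grm3, a metabotropic glutamate receptor, and the clock genes Nr1d2 and Dbp were lower. Sorcs3 (gene ID 294043) rose from 33.2 ± 2.40 to 52.2 ± 0.397 CPM (n = 3 per group; log2 fold change 0.65, SE 0.072, edgeR Benjamini-Hochberg adjusted p = 0.0027). Grm3 (gene ID 24416) fell from 402 ± 46.5 to 219 ± 9.74 CPM (log2 fold change −0.87, SE 0.10, edgeR adjusted p = 0.0027), and all of these calls remained with the length offset.

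The other large changes spanned several kinds of gene. Cyp26b1 (gene ID 312495) rose from 6.71 ± 1.08 to 17.7 ± 3.83 CPM (log2 fold change 1.40, SE 0.16, edgeR adjusted p = 0.0027). Dohh rose from 37.7 ± 6.74 to 82.0 ± 11.2 CPM (1.12, SE 0.13). Gfy, a Golgi protein of olfactory neurons, rose from 0.601 ± 0.35 to 2.85 ± 0.193 CPM, a 4.73-fold increase. Cyc1, a cytochrome subunit of the respiratory chain, rose by a log2 of 0.79 (SE 0.096) and Rprm, a cell cycle inhibitor marking deep cortical layers, by 1.07 (SE 0.16). Gprc5a, Prr15, Myl4 and the pseudogene Mettl9-ps1 rose by 1.51, 1.35, 1.01 and 1.05, each from below 2 CPM in Control, and counts of Mettl9-ps1 could not be separated from those of its parent gene. Among called genes that met the naming rule and fell, Zbtb20, a zinc finger transcription factor, had the largest log2 fold change (−1.57, SE 0.32, from 13.5 ± 2.80 to 4.53 ± 0.719 CPM, edgeR adjusted p = 0.025). Its call stayed in only 4 of 9 fits that each left out a library, with an edgeR adjusted p of up to 0.091. Galnt4, which starts O-glycosylation, Slc22a3, a transporter of organic cations and monoamines, Epb4.1l5 and Zfp366 fell by 1.26, 1.23, 1.19 and 1.18 on the log2 scale. Stil, Hmcn1 and the transfer RNA gene Trne fell by 1.06, 0.94 and 0.93. Pura, a nucleic acid binding protein, fell by 0.65 and Ogfrl1 by 0.58, both with edgeR adjusted p = 0.0027. Prr15 and Mettl9-ps1 were no longer called with the length offset (edgeR adjusted p = 0.052 and 0.059), whereas the others of this paragraph were. In the 9 fits that each left out a library, Gprc5a, Prr15, Mettl9-ps1 and Trne stayed called in only 5. Stil stayed called in 6 of them, and Epb4.1l5 and Zfp366 in 7.

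**Figure D2:**
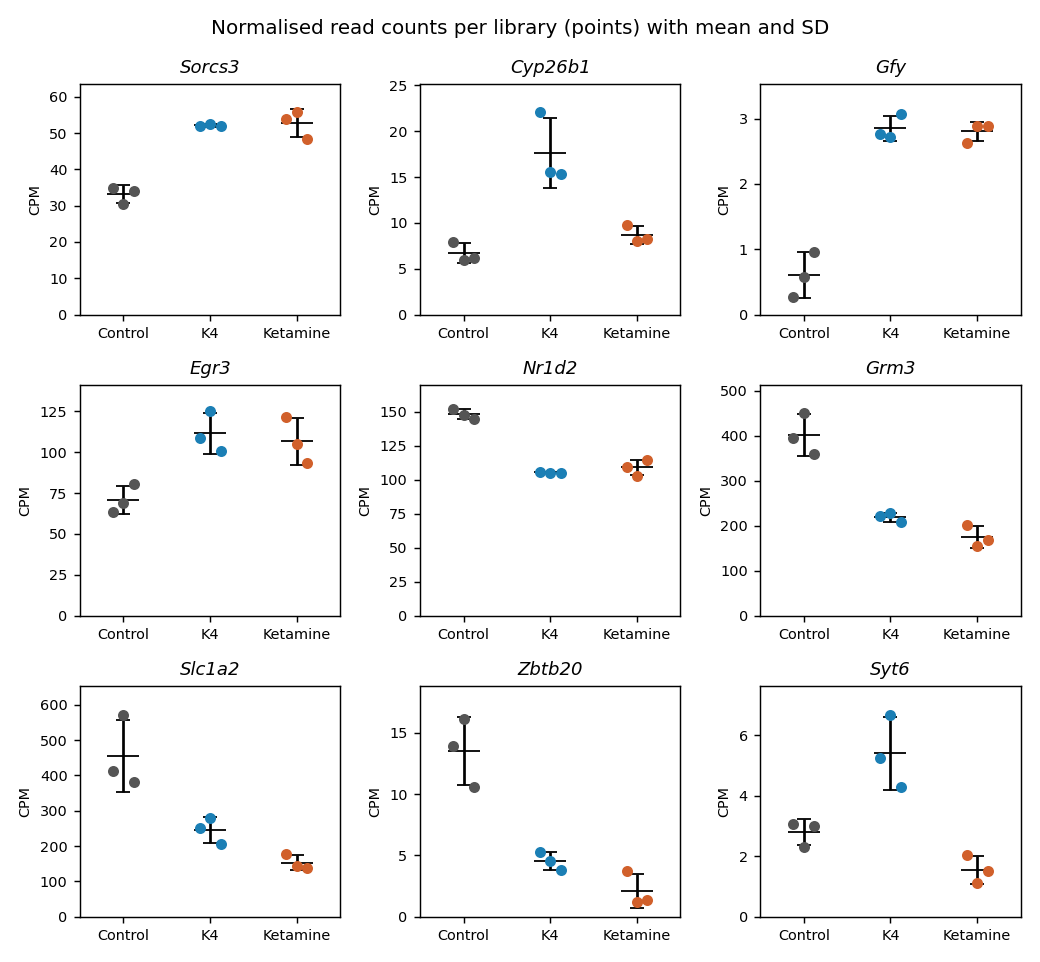
Normalised read counts (vertical axes, CPM) of 9 genes in each library, with the mean and SD of each group of 3. Sorcs3, Gfy and Egr3 lay higher and Nr1d2, Grm3, Slc1a2 and Zbtb20 lower in both treated groups than in Control, whereas Syt6 lay higher in K4 and lower in Ketamine.

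Of the 15 clock genes, 8 fell and 1 rose after K4 (9 and 1 adjusted over the list alone), with a median log2 fold change of −0.31 (camera adjusted p = 4.4e-09, and adjusted p = 0.015 with an estimated correlation). Nr1d2, a nuclear receptor that represses clock transcription, fell from 148 ± 3.59 to 105 ± 0.55 CPM (log2 fold change −0.49, SE 0.056, edgeR adjusted p = 0.0027), and Dbp, a clock output factor, fell from 163 ± 9.95 to 110 ± 6.59 CPM (−0.57, SE 0.070). Bhlhe41 and Per2 fell by 0.45 and 0.44. Arntl, the activator that drives these genes, rose by 0.30 (edgeR adjusted p = 0.016) and was named after its value was seen. With the length offset 6 members stayed lower and 1 higher, and Per2 was no longer called (edgeR adjusted p = 0.064).

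Activity-regulated genes were higher as a list after K4 (median 0.39, camera adjusted p = 6.1e-05), although the adjusted p was 0.58 with an estimated correlation. Of its 28 members 25 had positive log2 fold changes, but only Egr3 and Nptx2 were called higher, also when adjusted over the list alone. Egr3, an immediate early transcription factor, went from 70.9 ± 8.59 to 112 ± 12.6 CPM (log2 fold change 0.65, edgeR adjusted p = 0.012), and Nptx2, a secreted synaptic pentraxin, from 26.3 ± 1.49 to 47.9 ± 5.26 CPM (0.86, edgeR adjusted p = 0.015). Bdnf had a log2 fold change of 0.37 (edgeR adjusted p = 0.125). Fos, Arc, Npas4 and Egr1 had values of 0.84, 1.01, 0.96 and 0.34 with intervals that span 0, Arc ranging from −0.78 to 2.79.

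Among synaptic and signalling lists, camera called 4 as lower after K4, each lost with an estimated correlation. In the neurotrophin and mTOR list 5 of 23 members fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.37 with an estimated correlation). Creb1 and Eef2k fell by 0.34 and 0.40, Ntrk2, the BDNF receptor, fell from 979 ± 189 to 695 ± 44.8 CPM (edgeR adjusted p = 0.030), and Vgf, a neuropeptide precursor, rose by 0.46. In the GABA list 4 of 19 fell (9 lower and 3 higher adjusted over the list alone; camera adjusted p = 0.0012, and adjusted p = 0.58 with an estimated correlation), namely the receptor subunits Gabrb1 (−0.33), Gabra2 (−0.35) and Gabrg1 (−0.53) and the transporter Slc6a11 (−0.46). In the postsynaptic density 2 of 26 fell, Nlgn1 (−0.30) and Dlg2 (−0.38), against 6 adjusted over the list alone (camera adjusted p = 0.0083, and adjusted p = 0.58 with an estimated correlation). In perineuronal nets, the matrix around inhibitory neurons, 4 of 12 fell both ways (camera adjusted p = 0.011, and adjusted p = 0.58 with an estimated correlation), namely the link protein Hapln1 (−0.75), Vcan (−0.63), Ptprz1 (−0.69) and Ncan (−0.29). In the 9 fits that each left out a library, Slc6a11 stayed called in only 2, and Gabrg1 and Ncan in 3. Ntrk2, Nlgn1, Dlg2 and Ptprz1 stayed called in 5 of them. With the length offset Eef2k, Vgf, Gabra2 and Hapln1 remained, while Creb1, Ntrk2, Gabrb1, Gabrg1, Slc6a11, Nlgn1, Dlg2, Vcan, Ptprz1 and Ncan did not. Of the 4 lists only GABA was still called then (camera adjusted p = 0.0083), while the neurotrophin median went from −0.07 to −0.02 (camera adjusted p = 0.38), the postsynaptic density from −0.13 to −0.07 (camera adjusted p = 0.096) and perineuronal nets from −0.18 to −0.09 (camera adjusted p = 0.070).

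Several lists were not called by camera after K4. Grm3 and Grm5 (−0.37) fell among 7 metabotropic glutamate receptors, also when adjusted over the list alone. Grik2 (−0.34) fell among 17 ionotropic receptors (2 lower and 1 higher adjusted over the list alone). Grin1, the obligatory NMDA receptor subunit, had a value of 0.25 (edgeR adjusted p = 0.051), and Grin2a, Grin2b, Gria1 and Gria2 had −0.04, −0.13, 0.08 and −0.20. Rims1 (−0.46) fell among 24 synaptic vesicle genes, with 2 lower adjusted over the list alone. Htr6 rose (0.51) and Adra1a fell (−0.41) among 21 monoamine receptors (2 and 1 adjusted over the list alone). Pdyn, the dynorphin precursor, rose by 0.40 among 8 opioid genes, also adjusted over the list alone. Of 16 glucocorticoid and stress-axis genes, the receptors Nr3c1 (−0.31) and Nr3c2 (−0.25) fell and Crhbp rose by 0.46 (2 lower and 3 higher adjusted over the list alone). None of 26 ion channels was called by either count, while 3 were called higher with the length offset, where the list changed from lower (camera adjusted p = 0.40) to higher (camera adjusted p = 0.10). None of 18 interferon genes was called by either count, the median (−0.03) differing in sign from the mean (0.18) and the test (higher, camera adjusted p = 0.88), with Psmb8 at 0.62. The synaptic vesicle list was called higher with the length offset (camera adjusted p = 0.038). For it an estimated correlation gave camera adjusted p = 0.70 without the offset, and was not tried with the offset. Of the called genes in this paragraph only Grm3 and Pdyn remained with the length offset, and Grin1 was then called higher (edgeR adjusted p = 0.039). In 9 fits that each left out a library, Htr6 and Nr3c2 stayed called in only 1, and Grik2 in 2. Grm5, Rims1 and Adra1a stayed called in 4, Pdyn, Nr3c1 and Crhbp in 5, and Grm3 in all 9.

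The remaining groups were lists with mostly short transcripts and markers of glia and vessels. Among 60 tested oxidative phosphorylation genes, whose median implied length was 0.762 kb, 9 rose and none fell (11 adjusted over the list alone; camera adjusted p = 6.4e-11, and adjusted p = 0.58 with an estimated correlation), such as Atp5d (0.33), Uqcr11 (0.35), Cox7b (0.36) and Cox7c (0.38). None of the 60 was called with the length offset. Of 79 ribosomal protein genes, Rps9 (0.43) and Rps27 (0.38) rose, 1 adjusted over the list alone, with camera adjusted p = 4.1e-05 (adjusted p = 0.70 with an estimated correlation), and the list's direction turned with the length offset. Heat shock genes were higher by camera (median 0.14, adjusted p = 0.0057, and adjusted p = 0.58 with an estimated correlation) with none of 15 called, 2 adjusted over the list alone, and Hspe1 at 0.28. By camera with the preset correlation, astrocyte, oligodendrocyte precursor and vascular lists were lower beside these groups, whereas oligodendrocyte markers were higher. In astrocytes 2 of 12 fell (5 adjusted over the list alone; camera adjusted p = 0.0013, and adjusted p = 0.58 with an estimated correlation), Slc1a2, the main glutamate transporter, going from 456 ± 102 to 245 ± 37.4 CPM (edgeR adjusted p = 0.019) and the water channel Aqp4 by −0.53. In endothelial and mural cells 3 of 15 fell (4 adjusted over the list alone; camera adjusted p = 0.0036, and adjusted p = 0.58 with an estimated correlation), namely Rgs5 (−0.83), Abcb1a (−0.67) and Flt1 (−0.59). In oligodendrocyte precursors Sox6 (−0.67) fell among 10, with 3 adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.70 with an estimated correlation). In oligodendrocytes Cldn11, a tight junction protein of myelin, rose by 0.41 among 14, also adjusted over the list alone, and the list was higher (camera adjusted p = 0.027, and adjusted p = 0.70 with an estimated correlation). In the 9 fits that each left out a library, Aqp4 stayed called in only 2, Flt1 in 3 and Cldn11 in 4. Slc1a2, Rgs5 and Abcb1a remained with the length offset, and Aqp4, Flt1, Sox6 and Cldn11 did not, at −0.45, −0.47, −0.45 and 0.38. The medians of these lists moved little with it, from −0.32 to −0.29 in astrocytes, −0.17 to −0.15 in endothelial and mural cells, −0.25 to −0.21 in precursors and 0.18 to 0.19 in oligodendrocytes, although the precursor list lost its call (camera adjusted p = 0.062).

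In all, edgeR called 1095 of 18047 genes for K4 against Control, 409 higher and 686 lower (527 and 563 with upper quartile scaling, and 503 and 215 with the deposited FPKM at a mean of at least 1, where most calls were higher), with 4245 at an unadjusted p below 0.05. The median absolute log2 fold change of the calls was 0.36, and 173 exceeded 1.5-fold. The count was 427 with the length offset, 359 of them among the 1095, and it fell to 174 without Control replicate 1, to 239, 346 and 228 without K4 replicates 1, 2 and 3, and to 721 and 698 without Ketamine replicates 2 and 3. Of 70 named genes called here, 19 stayed called whichever library was left out, among them Sorcs3, Cyp26b1, Dohh, Gfy, Cyc1, Rprm, Grm3, Nr1d2, Dbp, Bhlhe41 and Hapln1. The other 9 ways to split the 6 libraries 3 and 3 gave 6 to 18 called lists (median 13) against 14 in the real comparison. A list call with the preset correlation therefore does not by itself mark a difference between these groups.

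Ketamine against Control asks the same of ketamine. Taok1, a protein kinase, Grm3, Slc1a2 and Zbtb20 were lower, and Sorcs3, Dohh, Gfy and Nedd8, a ubiquitin-like modifier, were higher. Grm3 fell from 402 ± 46.5 to 175 ± 24.1 CPM (n = 3 per group; log2 fold change −1.20, SE 0.10, edgeR Benjamini-Hochberg adjusted p = 0.00033). Slc1a2 (gene ID 29482) fell from 456 ± 102 to 153 ± 20.4 CPM (−1.57, SE 0.17, edgeR adjusted p = 0.00064). Sorcs3 rose from 33.2 ± 2.40 to 52.7 ± 3.85 CPM (0.67, SE 0.072, edgeR adjusted p = 0.00034), and these calls remained with the length offset.

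Taok1 (gene ID 286993) fell from 73.2 ± 1.81 to 36.6 ± 5.41 CPM (interval of the log2 fold change −1.19 to −0.81, edgeR adjusted p = 0.00033). Zbtb20 fell from 13.5 ± 2.80 to 2.11 ± 1.41 CPM (−2.67, SE 0.35). The pericyte regulator Rgs5, the cholinesterase Bche, the cell cycle kinase Cdk6, the integrin subunit Itga1, and Ccdc170 fell by 1.47, 1.65, 1.70, 1.62 and 1.65 on the log2 scale, and Zfp366 from 6.81 ± 2.26 to 2.41 ± 0.561 CPM. Ptpn4, a tyrosine phosphatase, fell by 0.58 and Ogfrl1 by 0.72 (edgeR adjusted p = 0.00034 for both). Nedd8 rose from 59.3 ± 1.67 to 85.2 ± 0.767 CPM (0.52, SE 0.053). Ccdc124 rose by 0.52 and Vps28, of the endosomal sorting machinery, from 51.2 ± 1.80 to 73.2 ± 2.85 CPM. Gfy rose from 0.601 ± 0.35 to 2.80 ± 0.15 CPM and Dohh from 37.7 ± 6.74 to 77.5 ± 5.68 CPM. Cpne1, Ada (adenosine deaminase), Gprc5a, Trim15, Tmprss5 and Tmem200b rose by 1.82, 1.76, 1.51, 1.30, 1.08 and 1.04, each from below 2 CPM in Control. Cpne1 and Ada were no longer called with the length offset (edgeR adjusted p = 0.0545 and 0.0645), whereas the other genes of this paragraph were. In the 9 fits that each left out a library, Ada and Tmprss5 stayed called in only 5 and Cpne1 in 6. Gprc5a and Tmem200b stayed called in 8 of them.

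Of the 15 clock genes, 7 fell and 1 rose after ketamine (11 and 1 adjusted over the list alone), with a median of −0.29 (camera adjusted p = 3.6e-05, but adjusted p = 0.055 with an estimated correlation). Nr1d2 fell from 148 ± 3.59 to 109 ± 5.77 CPM (log2 fold change −0.44, SE 0.056, edgeR adjusted p = 0.00058). Per2 and Per3, repressors of the clock, fell by 0.47 and 0.48, and Arntl rose by 0.33 (edgeR adjusted p = 0.0037). All but Per2 (edgeR adjusted p = 0.056) remained with the length offset.

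**Figure D3:**
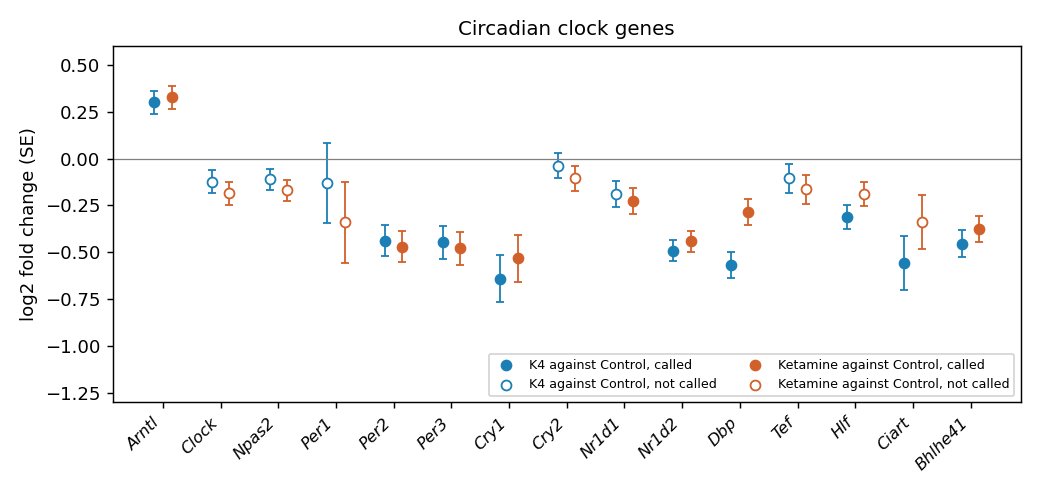
Log2 fold change against Control (vertical axis, bars are standard errors) of the 15 listed clock genes for K4 and Ketamine, with filled points for called genes. Arntl lies at 0.30 and 0.33, and the called Per, Cry, Nr1d and output genes lie below 0.

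Camera called 6 lists of synaptic, receptor, neurotrophin and perineuronal net genes as lower after ketamine, and each call was lost with an estimated correlation. In the postsynaptic density 10 of 26 fell and 1 rose (14 and 1 adjusted over the list alone; camera adjusted p = 7.2e-05, and adjusted p = 0.34 with an estimated correlation), with Shank1, a scaffold of excitatory synapses, going from 805 ± 145 to 425 ± 70.6 CPM (edgeR adjusted p = 0.0018) and Dlg2 (−0.50), Iqsec2 (−0.37) and Dlgap2 (−0.40) below it. In the GABA list 7 of 19 fell and 1 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.0014, and adjusted p = 0.34 with an estimated correlation), including Gad2, which makes GABA (−0.63), Gabrb1 (−0.52), Gabra2 (−0.38) and the transporter Slc6a11 (−0.72). In the neurotrophin and mTOR list 10 of 23 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 0.00014, and adjusted p = 0.055 with an estimated correlation), with Ntrk2 at −0.70 (979 ± 189 to 603 ± 41.2 CPM, edgeR adjusted p = 0.0024), Gsk3b at −0.32 and Rictor at −0.34. In perineuronal nets 5 of 12 fell (6 adjusted over the list alone; camera adjusted p = 9.9e-05, and adjusted p = 0.26 with an estimated correlation), with Hapln1 at −0.77, Ncan at −0.50, Vcan at −0.84 and Ptprz1 at −0.84. Among 17 ionotropic receptors 5 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0055, and adjusted p = 0.51 with an estimated correlation), with Grik1 (−0.45), Grin2d (−0.67), Grik2 (−0.28) and Grik3 (−0.49) lower and Grin1 higher (0.23, edgeR adjusted p = 0.039). The Grin1 call stayed in only 1 of 9 fits that each left out a library, with an edgeR adjusted p of up to 0.15. Grik3 stayed called in 4 of these fits, Grik2 in 5, Grin2d in 7 and Grik1 in 8. Grin2a, Grin2b, Gria1 and Gria2 had values of −0.43, −0.15, −0.03 and −0.16. Grm3 and Grm5 (−0.49) fell among 7 metabotropic receptors, also adjusted over the list alone (camera adjusted p = 0.040, and adjusted p = 0.41 with an estimated correlation). With the length offset Dlg2, Gabrb1, Gsk3b, Rictor, Grin2d, Grik2 and Grik3 were no longer called, and the other members named here as called stayed called. Under it the ionotropic and metabotropic lists lost their calls (camera adjusted p = 0.28 for both, medians −0.08 and −0.02), and the medians of the called lists went from −0.20 to −0.09 in the postsynaptic density, −0.16 to −0.10 for GABA, −0.22 to −0.06 for neurotrophin and mTOR signalling and −0.39 to −0.29 in perineuronal nets.

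Of 26 ion channels 8 fell and 1 rose by either count after ketamine (camera adjusted p = 0.0019, and adjusted p = 0.60 with an estimated correlation), among them Kcnq3 (−0.63) and Kcna1 (−0.59), which set neuronal excitability, Scn8a (−0.45) and Scn1a (−0.33). The direction of this list turned with the length offset, under which Kcnq3 and Kcna1 remained. Of 24 synaptic vesicle genes 5 fell and 2 rose by either count, including the active zone proteins Bsn (−0.52), Pclo (−0.65) and Rims1 (−0.64) and, higher, Syp (0.41), and the median (0.09) and test (higher, camera adjusted p = 0.94) differed in sign from the mean (−0.04). Among 21 monoamine receptors Adra1a fell (−0.89) and Adra1d rose (0.50) by either count, the median (0.08) and test (higher, camera adjusted p = 0.87) differing in sign from the mean (−0.01). Pdyn rose by 0.40 among 8 opioid genes (1 higher and 1 lower adjusted over the list alone). Nr3c1 (−0.38) and Nr3c2 (−0.26) fell and Crhbp rose (0.34) among 16 glucocorticoid and stress-axis genes by either count, where the median (0.04) differed in sign from the mean (−0.01) and the test (lower, camera adjusted p = 0.96). Egr3 (0.59) and Nptx2 (0.74) rose among 28 activity-regulated genes by either count (camera adjusted p = 0.079), and Bdnf, Fos, Arc, Npas4 and Egr1 had values of 0.29, 0.43, 0.49, 1.12 and −0.13. None of 18 interferon genes was called by either count, with Ifit2 at −0.74. Crhbp stayed called in only 2 of 9 fits that each left out a library, and Scn1a in 5. Bsn, Pclo, Scn8a, Scn1a, Nr3c1, Nr3c2 and Crhbp were no longer called with the length offset, under which the activity-regulated list was called higher and the interferon list lower (camera adjusted p = 0.041 for both). For these lists an estimated correlation gave camera adjusted p = 0.79 and 0.85 without the offset, and it was not tried with the offset.

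Of 60 oxidative phosphorylation genes 33 rose and none fell (46 adjusted over the list alone; camera adjusted p = 1.1e-18, and adjusted p = 0.26 with an estimated correlation), such as Atp5d (0.42), Uqcr11 (0.45), Ndufb3 (0.47) and Ndufa4 (0.38), and 3 were called with the length offset. Of 79 ribosomal protein genes 12 rose by either count (camera adjusted p = 1.0e-08, and adjusted p = 0.60 with an estimated correlation), such as Rpl23 (0.38), Rps9 (0.40), Rpl36 (0.42) and Rpl41 (0.44), but the direction of the list turned with the length offset, under which none was called higher. Of 15 heat shock genes Hspa8 (0.30) and Hspe1 (0.32) rose by either count (camera adjusted p = 0.0059, and adjusted p = 0.51 with an estimated correlation), and neither remained with the length offset. By camera with the preset correlation, astrocyte, vascular, precursor and oligodendrocyte lists were lower in the same libraries. Among astrocyte markers 6 of 12 fell by either count (camera adjusted p = 0.00026, and adjusted p = 0.51 with an estimated correlation), including Aqp4 (−0.69), Slc1a3 (−0.63) and Gja1 (−0.51) beside Slc1a2. Among endothelial and mural markers 6 of 15 fell (8 adjusted over the list alone; camera adjusted p = 4.3e-07, and adjusted p = 0.34 with an estimated correlation), including the drug efflux pump Abcb1a (71.5 ± 15.7 to 35.8 ± 3.84 CPM), Flt1 (−0.96) and Vwf (−0.87) beside Rgs5, and 6 were lower with the length offset too. Among precursor markers 4 of 10 fell by either count (camera adjusted p = 0.00047, and adjusted p = 0.51 with an estimated correlation), Sox6 (−0.88), Gpr17 (−0.79), Pdgfra (−0.65) and Cspg4 (−0.59). Among oligodendrocyte markers Ugt8 (−0.48), Ermn (−0.61) and Fa2h (−0.51) fell of 14 by either count (camera adjusted p = 0.020, and adjusted p = 0.68 with an estimated correlation). Slc1a3, Gja1, Pdgfra, Cspg4 and Fa2h were no longer called with the length offset, at −0.55, −0.47, −0.46, −0.35 and −0.52. In the 9 fits that each left out a library, Fa2h stayed called in only 3, Ermn in 4 and Cspg4 in 5.

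In all, edgeR called 3013 genes for Ketamine against Control, 1254 higher and 1759 lower (1587 and 1549 with upper quartile scaling, and 1690 and 988 with the deposited FPKM at a mean of at least 1, where most calls were higher), with 5640 at an unadjusted p below 0.05. The median absolute log2 fold change of the calls was 0.37, and 595 exceeded 1.5-fold. The count was 1381 with the length offset, 1139 of them among the 3013, and it fell to 1811 without Control replicate 1 and to 1177 and 1556 without Ketamine replicates 2 and 3. Of 100 named genes called here, 68 stayed called whichever library was left out. The other 9 splits of the 6 libraries gave 10 to 14 called lists (median 13) against 17 in the real comparison.

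The responses to both treatments were also set side by side, since the series concerns effects that last after treatment. Sorcs3, Dohh, Gfy, Egr3, Nptx2 and Arntl rose and Grm3, Zbtb20, Slc1a2, Rgs5, Nr1d2 and Per2 fell after both. The K4 calls of Sorcs3, Dohh, Gfy, Grm3 and Nr1d2 stayed in all 9 fits that each left out a library. Those of Egr3 stayed in 8, Slc1a2 and Per2 in 7, Nptx2 and Rgs5 in 6, and Zbtb20 in 4. In total 335 genes rose and 585 fell in both comparisons, which share their Control libraries, and no value of this overlap without a treatment effect was computed. The exception was Syt6, which was called higher after K4 (0.95, SE 0.22, edgeR adjusted p = 0.029) and lower after ketamine (−0.84, edgeR adjusted p = 0.032). Its K4 call was lost with the length offset (edgeR adjusted p = 0.055) and stayed in 6 of 9 fits that each left out a library, with an edgeR adjusted p of up to 0.11.

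**Figure D4:**
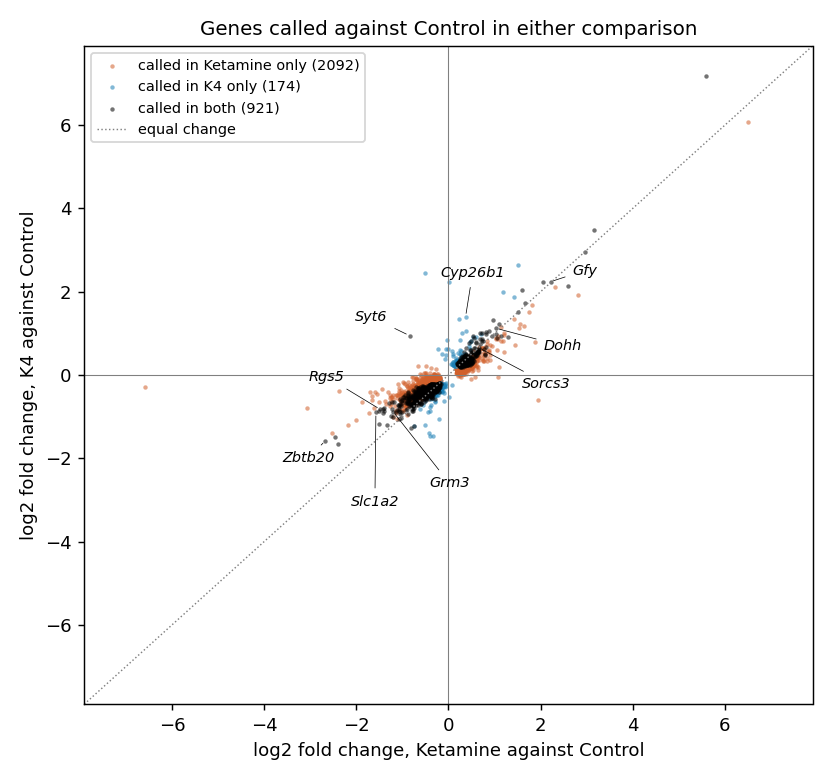
Log2 fold change against Control for Ketamine (horizontal axis) and K4 (vertical axis) of the 3187 genes called in either comparison, coloured by where they were called, with a dotted line of equal change. Gfy and Sorcs3 lie higher and Grm3 and Zbtb20 lower in both, and Syt6 lies at 0.95 for K4 and −0.84 for Ketamine.

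Across all 18047 genes, which are not independent replicates, the fold changes of group means correlated with Pearson's r = 0.668 and Spearman's rho = 0.708. In 20 simulations without a treatment effect, with simulated Control libraries shared in the same way, the values were 0.480 ± 0.011 and 0.438. All 9 libraries were drawn there from a single mean and a single dispersion per gene, with genes independent. In the data the mitochondrial share had a larger SD in Control (3.68%) than in K4 (0.518%) and Ketamine (0.652%). A larger spread in Control would raise the simulated values, so the excess may be overstated. The covariance was 0.0840 against a simulated 0.0279 ± 0.00097, a difference of 0.0561. The signs matched for 79.4% of genes against a simulated 66.2%. With 3 Control libraries no split leaves 2 in each part, so part of the excess may come from the shared libraries. An F test over all 3 groups in edgeR called 2205 genes, with 5080 at an unadjusted p below 0.05.

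K4 against Ketamine asks whether the treated groups differed a week after treatment ended. No gene passed the threshold in edgeR. The values that came nearest were higher in K4 for Syt6, a synaptotagmin of deep cortical layers, Sema5a, an axon guidance protein, Cdhr1, Cyp26b1 and Caln1. Syt6 (gene ID 60565) stood at 5.40 ± 1.19 CPM in K4, 1.55 ± 0.474 in Ketamine and 2.80 ± 0.422 in Control (n = 3 each; log2 difference 1.79, interval 1.27 to 2.31, edgeR Benjamini-Hochberg adjusted p = 0.078). Cyp26b1 stood at 17.7 ± 3.83 and 8.69 ± 0.975 CPM (1.02, interval 0.68 to 1.37, edgeR adjusted p = 0.097).

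Sema5a, Cdhr1 and Caln1 had log2 differences of 0.55, 0.85 and 0.55 (edgeR adjusted p = 0.082, 0.082 and 0.097). On the lower side Nol7, Shfm1, Tceal5 and Ccnyl1 had −0.30, −0.32, −0.34 and −0.35, and Rasgef1c stood at 27.7 ± 0.435 CPM in K4 and 34.6 ± 1.42 in Ketamine. Slc1a2 and Grm3, lower against Control after both treatments, had 0.68 (interval 0.31 to 1.05) and 0.33 (0.11 to 0.54). Kcna1, Vwf, Grik3 and Nos1 had 0.59, 0.71, 0.71 and 0.48. The intervals of Bdnf (−0.21 to 0.37), Ntrk2 (−0.04 to 0.45), Grin1 (−0.13 to 0.17), Grin2b (−0.15 to 0.18), Gria1 (−0.04 to 0.26) and Gria2 (−0.22 to 0.13) left room for small differences either way, and those of Fos (−1.10 to 1.91) and Egr1 (−0.43 to 1.38) for large ones, as did the SE of 0.73 for Arc (0.51) and of 0.56 for Npas4 (−0.16). Grin2a had 0.39 (0.06 to 0.71).

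Among lists, oligodendrocyte genes stood out, with Myrf, a transcription factor of myelination, at 0.60 and 10 of 14 higher in K4 adjusted over the list alone, although none over all genes (camera adjusted p = 2.0e-14, and adjusted p = 0.36 with an estimated correlation). Adjusted over the list alone, 6 of 16 excitatory layer markers, 4 of 12 perineuronal net genes and 3 of 15 endothelial and mural markers were also higher in K4. In the clock list 1 gene, Dbp (−0.28), was lower adjusted over the list alone, and the median (0.03) differed in sign from the mean (−0.02) and the test (lower, camera adjusted p = 0.39). Heat shock genes had none called by either count and a median of −0.02 beside a mean of 0.00 (lower, camera adjusted p = 0.52), with Dnajb1 at −0.14. Metabotropic receptors (camera adjusted p = 0.23; 1 higher adjusted over the list alone), synaptic vesicles (0.096; 2 higher), monoamine receptors (0.24; 1 higher, Adra1a at 0.48), opioid genes (0.096; 1 higher, Oprm1 at 1.16), GABA (0.49; none, Gabrb1 at 0.20), stress-axis genes (0.86; none, Crh at 0.31) and astrocyte markers (0.096; 1 higher) were not called by camera. Of the lists it called, ionotropic receptors and ion channels had 1 gene higher each adjusted over the list alone, and activity-regulated, postsynaptic density, neurotrophin, interferon, oxidative phosphorylation, ribosomal and precursor lists had none, with Fosl2 at 1.14, Shank1 at 0.43, Igf1 at 0.32, Psmb8 at 0.45, Ndufs3 at −0.21, Rpl23 at −0.16 and Gpr17 at 0.34. In all, camera called 14 of 29 lists, 12 higher and 2 lower in K4, none with an estimated correlation, and with the length offset 15, all higher, as opioid, microglia and striatal lists were added and oxidative phosphorylation and ribosomal lists were lost. The other 9 splits of the 6 libraries gave 2 to 15 (median 8).

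The count of 0 stood beside 1648 genes at an unadjusted p below 0.05, 71 calls by DESeq2, 40 by limma-voom, 27 when edgeR was given only the 6 libraries or left out Ketamine replicate 1, and 12 without Control replicate 2. The treatments differed in route as well as in compound, and doses are not given, so a difference between compounds was not measured apart from these.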

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

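Chosen after the results were seen were the tests of the calls that remain with the length offset, of thinned counts, of the clock genes and of the fold changes shared by both treatments, while the splits of the libraries and the bounds for calls that end with the length offset were set earlier.

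Calls against Control came with a length trend between the libraries. After the length offset 32.8% (K4) and 37.8% (Ketamine) of the calls remained, and 87.7% and 91.2% remained after thinning to the smallest library total, so neither the trend nor depth alone accounts for all of them. In calls that ended with the offset, the median absolute log2 fold change was 69.2% (K4) and 54.1% (Ketamine) of that without it, between the bounds, which leaves open how much of each was the trend. For K4 1 of 10 splits of the libraries gave a count as large (1095 against 37 in the highest other), for Ketamine 1 of 10 (3013 against 1), and 10 splits cannot give a share below 0.05. Over all 3 groups it was 1 of 100 (2205 against 1685), the other splits being drawn at random. The 3 highest other counts (1685, 1616 and 894) came from splits that kept the 3 Control libraries together and mixed K4 with Ketamine. The next highest was 35, so this count mainly reflects Control against the rest. Treatment, handling for the cannula or injections, and preparation of the 3 Control libraries as a set could each lie behind the calls against Control and were not tested apart.

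Fold changes shared by K4 and Ketamine exceeded what shared Control libraries gave in simulation. That simulation drew all groups with the same spread per gene, which may understate what shared libraries give. The covariance was 0.0840 against a simulated 0.0279, but the Control libraries could not be divided between the comparisons, so shared libraries may still hold part of it. Under the length offset it was 0.0759, so the length trend alone is unlikely to account for it. A response common to both treatments and a difference of the Control set remain open.

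Of 15 clock genes 8 (K4) and 7 (Ketamine) were called lower against Control and 1 higher in each comparison, but with an estimated correlation the list was called only for K4 (camera adjusted p = 0.015, and 0.055 for Ketamine). With the length offset 6 members were called lower and 1 higher in each comparison, and the list had camera adjusted p = 1.8e-07 (K4) and 0.0011 (Ketamine) with the preset correlation, so the length trend alone is unlikely to account for these calls. The prediction set for another clock phase at dissection was Arntl, Clock and Npas2 called higher while Per, Nr1d and Dbp genes are called lower. Among Arntl, Clock and Npas2 only Arntl was called (0.30 and 0.33). Clock (−0.12 and −0.19) and Npas2 (−0.11 and −0.17), both named after their values were seen, were not. Whether a change of phase must raise all of them was not tested, so this test left another phase open. The time of dissection is not in the labels, so phase and treatment cannot be told apart.

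Between K4 and Ketamine 10 of 10 splits gave at least the 0 genes of the real comparison (highest other 1), which any split must, so that test carries no information. For lists 4 of 10 splits gave as many as K4 against Control (14, highest other 18), 1 of 10 as many as Ketamine against Control (17, highest other 14) and 2 of 10 as many as K4 against Ketamine (14, highest other 15).

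The remaining results are medians of log2 fold changes between K4 and Ketamine in lists called by camera. Activity-regulated genes had 0.17 (camera adjusted p = 0.0062; adjusted p = 0.69 with an estimated correlation; lower with camera adjusted p = 0.56 without K4 replicate 2, and 0.25 without Ketamine replicate 1). Ionotropic glutamate receptors had 0.11 (camera adjusted p = 0.00074; adjusted p = 0.36 with an estimated correlation). The postsynaptic density had 0.11 (camera adjusted p = 0.0020; adjusted p = 0.44 with an estimated correlation). Neurotrophin and mTOR signalling had 0.086 (camera adjusted p = 0.0017; adjusted p = 0.21 with an estimated correlation). Ion channels had 0.12 (camera adjusted p = 2.0e-05; adjusted p = 0.53 with an estimated correlation). Interferon genes had 0.29 (camera adjusted p = 0.014; adjusted p = 0.69 with an estimated correlation; lower with camera adjusted p = 0.22 without K4 replicate 3, and 0.33 without Ketamine replicate 1). Perineuronal nets had 0.14 (camera adjusted p = 0.0022; adjusted p = 0.36 with an estimated correlation). Oxidative phosphorylation had −0.093 (camera adjusted p = 1.5e-08; adjusted p = 0.37 with an estimated correlation; −0.016 and camera adjusted p = 0.079 with the length offset). Ribosomal proteins had −0.074 (camera adjusted p = 8.0e-05; adjusted p = 0.69 with an estimated correlation; higher with camera adjusted p = 0.81 with the length offset). Excitatory layer markers had 0.16 (camera adjusted p = 5.9e-08; adjusted p = 0.21 with an estimated correlation). Oligodendrocyte markers had 0.47 (camera adjusted p = 2.0e-14; adjusted p = 0.36 with an estimated correlation). Oligodendrocyte precursors had 0.21 (camera adjusted p = 0.014; adjusted p = 0.67 with an estimated correlation). Endothelial and mural markers had 0.29 (camera adjusted p = 5.2e-06; adjusted p = 0.36 with an estimated correlation). Blood cell markers had 0.76 (camera adjusted p = 6.0e-06; adjusted p = 0.36 with an estimated correlation).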

How the results depend on the processing

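The length offset, the thinned counts and the fits without Control replicate 2 and K4 replicate 2 are tests chosen after the results were seen, and where a value moved the cause was not tested.

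K4 against Control had 1095 calls. Other settings gave 1839 (DESeq2 test), 3927 (limma-voom with weights), 452 (only the 6 libraries), 2120 (adjusted p below 0.1), 173 (at least 1.5-fold), 7 and 34 (deposited FPKM plus 1, 5 higher and 2 lower, and plus 0.1, 26 higher and 8 lower), 718 (FPKM with mean at least 1, 503 higher and 215 lower), 1 (deposited TPM) and 427 (length offset). Upper quartile scaling gave 527 higher and 563 lower against 409 and 686. Leaving out a library gave 174 (Control 1) to 1548 (Control 2), with 239, 346 and 228 without K4 1, 2 and 3 and 721 and 698 without Ketamine 2 and 3.

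Ketamine against Control had 3013 calls. Other settings gave 5508 (limma-voom), 595 (at least 1.5-fold), 1569 and 1631 (FPKM plus 1, 926 higher and 643 lower, and plus 0.1, 977 higher and 654 lower), 537 (TPM, 354 higher and 183 lower) and 1381 (length offset). Leaving out a library gave 1177 (Ketamine 2) to 3191 (Control 3), with 1811 without Control 1 and 1556 without Ketamine 3, and leaving out Control 2 and K4 2 together gave 3296.

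K4 against Ketamine had 0 calls. Other settings gave 6 (no filter), 1 (at least 10 counts in every library), 71 (DESeq2), 40 (limma-voom), 27 (only the 6 libraries), 5 (adjusted p below 0.1), 1 each with FPKM plus 1, FPKM plus 0.1, FPKM with mean at least 1 and TPM, 5 without Control 2 and K4 2, and 4 (thinned). Leaving out a library gave 0 to 27 (Ketamine 1), with 12 without Control 2, 3 without Control 3 and 1 each without K4 2 and Ketamine 2.

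Over all 3 groups 2205 genes were called. Other settings gave 5495 (limma-voom), 3464 (adjusted p below 0.1), 525 and 590 (FPKM plus 1 and plus 0.1), 88 (TPM) and 895 (length offset). Leaving out a library gave 894 (Control 1) to 2492 (Control 2), with 906 without Ketamine 2 and 1097 without Ketamine 3, and leaving out Control 2 and K4 2 together gave 2537.

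Replicate numbers were not taken to pair the libraries, since the labels do not say that a number pairs them. Only 1 of 9 same-number correlations passed 0.1. As a hint from the data, not the design, all 9 were positive (0.0024 to 0.11, against −0.16 to 0.069 for other numbers across groups), and 6 of 9 libraries correlated best with their own number. With the number as a block edgeR called 1168, 3191, 1 and 2255 genes in the order above.

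Lists called were 14, 17 and 14. An estimated correlation gave 1, 0 and 0, fry gave 4, 9 and 1, and the length offset gave 10, 16 and 15. Leaving out a library gave 11 to 15, 15 to 20 and 12 to 16. The correlation of fitted fold changes was 0.689, with 0.876 in genes called in either comparison, 0.671 with the length offset and 0.530 (K4 1) to 0.727 (Control 1) leaving out a library. Choosing genes by their change against the same Control libraries can itself raise the 0.876. No value without a treatment effect was computed for that choice.

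Some results changed sign. With the length offset the ribosomal list had camera adjusted p = 0.38 (K4 against Control), 0.28 (Ketamine against Control) and 0.81 (K4 against Ketamine), and the channel list 0.95 (Ketamine against Control). For Ketamine against Control, Reln had 0.029 with the offset, and Cux1 had 0.020 with TPM. Leaving out a library gave the interferon list camera adjusted p = 0.00026 (without K4 3, sign changed) to 0.89 for K4 against Control and 3.78e-07 to 0.33 for K4 against Ketamine, with 0.22 and a changed sign without K4 3. For K4 against Ketamine it gave the activity-regulated list camera adjusted p = 6.12e-14 to 0.56 (without K4 2, sign changed) and the meningeal list 7.25e-05 to 0.56, with 0.038 and a changed sign without K4 2.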

Other observations

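Among the tests here, the length offset was chosen after the results were seen.

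Markers of other cells and of tissue next to the prefrontal cortex bear on what was dissected. Striatal markers had 3 of 10 higher after K4 (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.33), namely Ppp1r1b (0.45), Rgs9 (0.84) and Pde10a (0.39), and 1 after ketamine by either count (Ppp1r1b, 0.31; camera adjusted p = 0.94), and only Ppp1r1b and Pde10a after K4 remained with the length offset. In the 9 fits that each left out a library, the K4 calls of Pde10a and Rgs9 stayed in only 2. The call of Ppp1r1b stayed in 6 of them for K4 and in 4 for Ketamine. Between K4 and Ketamine 2 striatal markers were higher adjusted over the list alone (camera adjusted p = 0.093), with Pde10a at 0.45. Meningeal markers had none of 14 called by either count in any comparison, but the highest list medians against Control, 0.65 after K4 with 12 positive (camera adjusted p = 0.025, and adjusted p = 0.70 with an estimated correlation) and 0.75 after ketamine with 13 positive (camera adjusted p = 0.0028, and adjusted p = 0.60 with an estimated correlation). Between K4 and Ketamine the median was −0.13 (camera adjusted p = 0.076), and against Control Slc6a13 was at 0.68 and 0.61. Choroid plexus (camera adjusted p = 0.40, 0.87 and 0.52) and ependymal markers (camera adjusted p = 0.40, 0.64 and 0.90) had none called by either count. For ependymal markers between K4 and Ketamine the median (−0.01) differed in sign from the mean (0.13) and the test (higher). Blood cell markers had none of 7 called by either count, with medians of 0.12 after K4 (camera adjusted p = 0.42) and −0.64 after ketamine (camera adjusted p = 0.061, and 0.0014 with the length offset), and haemoglobin genes have near-identical copies. After ketamine an estimated correlation gave this list camera adjusted p = 0.66 without the offset, and was not tried with the offset.

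Interneuron markers had none of 14 called after K4 (2 higher adjusted over the list alone; camera adjusted p = 0.12), with Cck at 0.28. After ketamine Cck (0.56) and Pvalb (0.36) rose and Nos1 (−0.57) and Reln (−0.29) fell by either count (camera adjusted p = 0.14). Cck and Nos1 remained with the length offset and Pvalb did not, while Reln turned to 0.029 and stayed called in only 2 of 9 fits that each left out a library. Between them 1 was higher and 1 lower adjusted over the list alone, the median (−0.01) and test (lower, camera adjusted p = 0.86) differing in sign from the mean (0.01). Microglia markers had 1 of 14 lower after K4 by either count (P2ry12, −0.52; camera adjusted p = 0.32), 4 lower after ketamine (5 adjusted over the list alone; camera adjusted p = 0.079), among them Cx3cr1 (−0.46), P2ry12 (−0.60) and Csf1r (−0.43), and none between them (camera adjusted p = 0.16). The K4 call of P2ry12 stayed in only 2 of 9 fits that each left out a library. With the length offset 1 and 3 microglia markers remained lower, and only then, with the preset correlation, was the list called lower after both treatments (camera adjusted p = 0.037 and 0.00054, medians −0.09 and −0.33) and higher in K4 than in Ketamine (camera adjusted p = 0.021). Without the offset an estimated correlation gave camera adjusted p = 0.76, 0.72 and 0.69, and it was not tried with the offset.

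Excitatory layer markers had 2 of 16 higher, Rprm (1.07) and Syt6 (0.95), and 2 lower, Cux2 (−0.46) and Rorb (−0.44), after K4 (3 and 4 adjusted over the list alone; camera adjusted p = 0.40), of which Rprm and Cux2 remained with the length offset. After ketamine 6 fell (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.020, and adjusted p = 0.51 with an estimated correlation), among them Cux2 (−0.42), Rorb (−0.43), Rasgrf2 (−0.34) and Cux1 (−0.32). None of these 4 remained with the length offset, under which 2 members were lower and the list lost its call (median −0.12, camera adjusted p = 0.28).

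K4 replicate 2 lay at −43.2 on the second principal component, where the other libraries lay between −13.2 and 17.7, and its share of ribosomal RNA genes was 1.12% against 0.820% and 0.866% in the other K4 libraries. Control replicate 2 had the highest such share (1.40%) and the highest mitochondrial share (19.0%) of all libraries, and lay lowest on the first component, at −38.5.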
